A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

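Total RNA was extracted with Trizol from flash-frozen dorsal skin and sequenced as standard Illumina libraries, per the labels' protocols. The 6 libraries were grouped by the phenotype in the labels, 3 wild-type and 3 yellow mutant, all at an age of 45 days. Per the submitters' processing notes, Bowtie2 2.2.8 and TopHat2 2.1.1 were used, with no roles given. The counting tool, its treatment of reads shared between loci, strand use, genome build and annotation are not given in the sources used here. The deposited table holds raw read counts per gene and library and, from the authors, FPKM values for the same genes and libraries, per the file headers. It also holds the authors' mean FPKM per phenotype, in which 0 was replaced by 0.001 in the deposited values, the authors' log2 fold change of these means, and the authors' p-value and FDR for the same comparison, whose test is not given in the sources used here. The authors' fold changes, p-values and FDR were used only for the counts of genes given from their table. The authors' FPKM values entered the rule for named genes, the FPKM filter, the limma alternatives and the gene length implied by counts and FPKM.

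Of 41818 loci, 39019 carry NCBI gene numbers and 2799 carry MSTRG identifiers. The deposited table gives a symbol for 35085 and a product name for 40909. Of the NCBI numbers, 35457 were found in the NCBI RefSeq gene table of assembly USDA_OmykA_1.1, which was used only for reference names and for which genes neighbour each other. No coordinates are given because the build behind the counts is not named. Rainbow trout carry many duplicated genes, and each locus was counted separately.

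The design foresaw limma on log2(FPKM + 0.5) for a table without counts and edgeR for a table with counts. Raw counts were present, so edgeR was used. Genes were kept with filterByExpr (30691 genes, 1994 of them MSTRG loci, out of 39799 with a count), libraries were scaled with TMM factors, and the phenotypes were compared with glmQLFit and glmQLFTest without covariates. P-values were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Principal components and correlations used log2 CPM with a prior count of 2. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The pipeline was tested on simulated data, with counts drawn from the means and depths of these libraries and 200 genes changed. For the simulated comparison of 3 against 3 libraries over 30280 genes, edgeR called 79% of genes changed by a log2 of 1 and 98% of those changed by 2, with 14 false calls among 191. The changed genes were drawn from those with a mean above 1 CPM, so recovery of less abundant genes was not tested. Only those 200 genes were changed, in random directions, whereas 44.8% of tested genes differed in the data. The simulation therefore does not test how the results depend on the scaling.

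Total counts ranged from 15059101 to 19031878 per library. Where all libraries of a phenotype had no count, a fold is given as a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio of scaled counts is given with its exact 95% binomial (Clopper-Pearson) interval. Floors and intervals cover counting error only. Libraries of the same phenotype differed by more than sampling noise, with chi-square per degree of freedom between 3.88 and 23.1 over genes with at least 20 counts, so each was kept as a separate sample. Across 30649 genes, which are not independent replicates, the Spearman correlation of the log2 fold change with the gene length implied by counts and FPKM was -0.0655.

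The gene lists, the rule for named genes, the test and the processing alternatives were fixed before the data were examined, except for the alternatives named below as added later. The 20 lists (307 symbols) cover melanin synthesis and melanosome, melanophore regulators, pteridine and xanthophore, carotenoid and retinoid, purine synthesis and iridophore, Wnt signalling, epidermal keratin and junction, mucous cells, dermal collagen and scale, skeletal muscle, erythrocyte, leukocyte, interferon response, adipocyte and lipid storage, nerve and Schwann cell, cell cycle, immediate early and heat shock, circadian clock, oxidative phosphorylation, and ribosomal proteins. A locus belonged to a list when its symbol or its product name matched. In some families the symbol and product name in the table disagree. Lists were compared with all other tested genes by limma's camera with a preset correlation of 0.01, two-sided, adjusted over the 20 lists. With this setting 10 lists passed. With an estimated correlation 0 passed, and with fry, which asks only whether the genes of a list move one way, 12 passed. Counts of members are given over all genes tested and adjusted over the list alone. Counts for parts of a list, such as the mucin, keratin or immediate early loci, were chosen after the values were seen.

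Named genes were the 10 largest increases and the 10 largest decreases among genes past the threshold whose phenotypes did not overlap, with an authors' FPKM of at least 5 in either phenotype and a symbol or product name. Added to these were up to 4 members of each list with the smallest adjusted p, and all loci of 11 pigment symbols. The rule named 120 genes. Alternatives were limma on log2 FPKM with pseudocounts of 0.1 and 1, no filter or a filter at a mean FPKM of 2, quantile normalization, size factors, TPM, other variance settings, library weights, DESeq2, the replicate number as a block, leaving out each library in turn, and a fold threshold. Added after the data were seen were library totals without TMM, limma at a pseudocount of 0.5, members matched by both symbol and product name, and camera over the KEGG pathways named in the deposited table.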

Results

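RNA of the dorsal skin of rainbow trout (Oncorhynchus mykiss) was sequenced at an age of 45 days in 6 libraries, 3 from wild-type fish and 3 from a yellow colour mutant. The comparison of the 2 phenotypes asks which messenger RNAs differ between skins of different colour. The small RNA part of the same study was not analysed here. Total counts were 17668054, 15059101 and 17975192 in wild-type replicates 1 to 3 and 16334241, 19031878 and 18158152 in yellow mutant replicates 1 to 3. Between 36471 and 37044 of the 41818 loci in the table had a count in a given library. The labels do not say whether the 3 libraries of a phenotype came from separate fish, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as TMM-scaled CPM (counts relative to library size), as mean ± SD with n = 3 libraries per phenotype. Changes are log2 fold changes of the yellow mutant over the wild type with their standard error (SE), and adjusted p-values come from the edgeR quasi-likelihood test unless another test is named.

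Libraries of the same phenotype resembled each other more than libraries of different phenotypes. Across genes, the correlation of log2 CPM lay between 0.9813 and 0.9825 among wild-type libraries, between 0.9833 and 0.9846 among yellow mutant libraries and between 0.9251 and 0.9367 across the phenotypes. None of the 6 libraries (0) was nearest to a library of the other phenotype. Keratin genes took 7.23 ± 0.134% of the counts in the wild type and 3.27 ± 0.131% in the yellow mutant. The 10 most abundant genes of a library took 12.6 ± 0.455% and 9.06 ± 0.195% respectively. The TMM scaling factors also separated the phenotypes, at 0.9335 ± 0.0154 in the wild type and 1.072 ± 0.00929 in the yellow mutant.

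**Figure D1:**
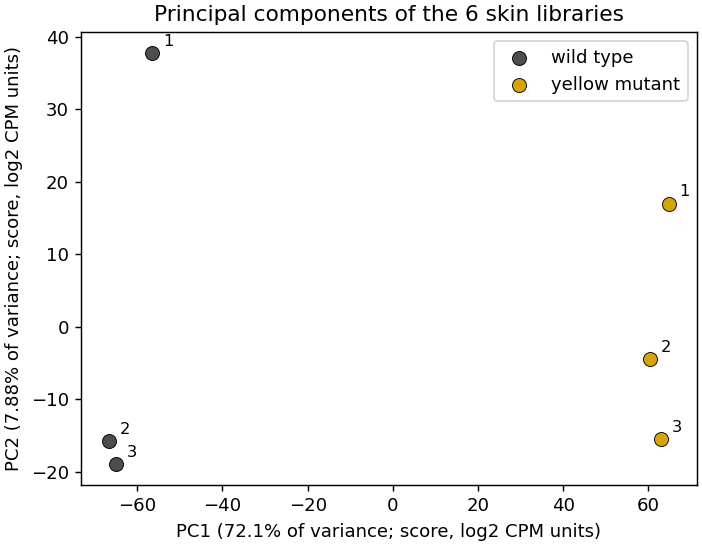
Principal components of log2 CPM over the tested genes, with 1 point per library, numbered by replicate and coloured by phenotype; axes are component scores. The first component (72.1% of the variance) separates the phenotypes, and the second (7.88%) sets replicate 1 of each phenotype apart from replicates 2 and 3.

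Skin of the yellow mutant carried more RNA of melanin genes (27 of 39 loci higher, 1 lower) and less RNA of keratin and cell junction genes (59 of 81 loci lower, 3 higher) than wild-type skin. Both lists passed camera with the preset correlation (adjusted p = 6.57e-11 and 1.17e-16), with adjusted p = 0.379 and 0.225 with an estimated correlation. Tyrosinase b (tyr, ncbi_100135828), a copy of the enzyme that starts melanin synthesis, stood at 59.8 ± 6.19 CPM in the yellow mutant and 15.9 ± 1.24 CPM in the wild type, a log2 fold change of 1.91 (SE 0.098, adjusted p = 1.46e-08). The most abundant of the named keratins, krt13 (ncbi_110495128), an intermediate filament gene of the epidermis, stood at 2798 ± 382 CPM and 11168 ± 436 CPM, and was 3.99-fold lower (SE of the log2 fold change 0.11, adjusted p = 2.8e-08). The circadian clock list was also lower (33 of 57 loci lower, 8 higher, camera adjusted p = 6.57e-11, adjusted p = 0.225 with an estimated correlation). In all, 13737 of 30691 tested genes (44.8%) differed at an adjusted p under 0.05, with 6658 higher and 7079 lower in the yellow mutant, and 16954 did not pass. With an absolute log2 fold change of at least 1 as well, 3515 genes remained, 1477 higher and 2038 lower. The levels of the 2 phenotypes did not overlap in 16667 tested genes (54.3%), against 10% given by chance with 3 libraries per group. The authors' deposited table lists 11091 genes with an FDR under 0.05, of which 5230 have a log2 fold change above 0 and 5861 below 0. Of 10817 such genes tested here, 10800 also differed in the edgeR test, 10797 of them with the same sign.

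The split between higher and lower genes depended on the scaling. With library totals alone in place of TMM factors, the median log2 fold change of all tested genes moved from -0.0029 to 0.1958, and 10805 genes were called higher and 4544 lower (70.4% higher, against 48.5% with TMM). All changes below are relative to the TMM scaling. The dermal collagen, erythrocyte, leukocyte, cell cycle, oxidative phosphorylation and ribosomal protein lists described below had medians below 0 with TMM and above 0 with library totals alone. None of those lists passed its test.

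Among genes that met the abundance rule, the largest increase was that of POLR2C (ncbi_110515744), a subunit of RNA polymerase II, with a log2 fold change of 6.53 (SE 0.46, adjusted p = 1.95e-07). It stood at 14.5 ± 3.47 CPM in the yellow mutant, and its 7 wild-type counts all fell in replicate 2. Without that library it was at least 159-fold higher, and without wild-type replicate 1 or 3 the fold was 60.8 or 61.2 in place of 92.7. The treatment of reads shared between copies of a gene is not given in the sources used here. Reads counted at another copy therefore cannot be told from a change in the RNA of this gene. Lox (ncbi_110525209), which crosslinks collagen, rose from 2.66 ± 0.571 to 56.0 ± 17.5 CPM (log2 fold change 4.41, SE 0.25). COL9A1 (ncbi_110496835), a cartilage collagen gene, rose from 303 counts in the wild type to 5750 in the yellow mutant (3.98, SE 0.23), and its log2 fold change was 4.57 without wild-type replicate 1. A proteoglycan 4-like locus (ncbi_110489645), a relative of the joint lubricant lubricin, rose by 3.78 (SE 0.19), and actinodin2 (ncbi_110530012), a component of the fibrils of fin folds, by 3.77 (SE 0.14). The remaining genes of this group were the natterin-like gene aep1 (ncbi_110492682, 4.21, SE 0.095), CYTL1 (ncbi_110534907, 3.89, SE 0.52), the HSP90 chaperone gene hsp90a.1 (ncbi_110529844, 3.72, SE 0.14), carm1 (MSTRG.19857, 3.65, SE 0.51) and a leucine-rich repeat extensin-like locus (ncbi_110489021, 3.49, SE 0.15). CYTL1 and carm1 rested on few wild-type counts, 31 and 8 in total. The log2 fold change of CYTL1 was 3.27 without wild-type replicate 1 and 4.51 without replicate 3, and leaving out wild-type replicate 3 left carm1 with 2 wild-type counts.

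Of the 10 largest decreases named by the same rule, 3 were at loci with no count in any yellow mutant library. With a floor of 3 counts over the group, a locus with a DEF1-like product (MSTRG.8355, 16.5 ± 3.28 CPM in the wild type) was at least 318-fold lower. The trypsin-3-like KLK9 (ncbi_110526453, 15.7 ± 2.94 CPM) was at least 303-fold lower, and Arpp19 (ncbi_110506780, 8.17 ± 0.701 CPM) at least 157-fold lower. These floors cover counting error only. Reads counted at another copy of a gene cannot be told from a loss of its RNA, which limits all folds in this paragraph. PRSS27 (ncbi_110522135), a serine protease gene, fell by 6.63 on the log2 scale (SE 0.45). Its 4 yellow mutant counts all came from replicate 2, without which it was at least 92.8-fold lower. PTGS2 (ncbi_110521832), which encodes the inducible cyclooxygenase of prostaglandin synthesis, stood at 0.446 ± 0.373 CPM in the yellow mutant and 21.4 ± 2.68 CPM in the wild type (log2 fold change -5.54, SE 0.26, adjusted p = 8.36e-09), and at -6.44 without yellow mutant replicate 3. FOS (ncbi_110529275), a growth-factor-induced transcription factor gene, fell by 4.84 (SE 0.35) and chs-2 (ncbi_110487593) stood at -4.40 (SE 0.27). TUBB4B (ncbi_110486715), a beta-tubulin gene, fell by 5.58 (SE 0.28), with -6.29 without yellow mutant replicate 1. S100P (ncbi_110500749), a calcium-binding protein gene, fell by 5.44 (SE 0.44) and kept 2 yellow mutant counts without replicate 1. A fish-egg lectin locus (ncbi_110499748) fell by 5.12 (SE 0.74), with -4.12 without wild-type replicate 2, in which it was most abundant.

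Genes of melanin synthesis and the melanosome were higher in the yellow mutant. Of 39 measured loci on this list, 27 rose, 1 fell and 11 did not pass (29 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.95. The list passed camera with the preset correlation (adjusted p = 6.57e-11), and adjusted p = 0.379 with an estimated correlation. Besides tyrosinase b, the other tyrosinase locus (tyr, ncbi_100135825) rose by 1.27 (SE 0.13). PMEL (ncbi_110528226), which forms the fibrils on which melanin is laid down, rose from 239 ± 25.4 to 513 ± 30.5 CPM (log2 fold change 1.11, SE 0.094, adjusted p = 9.49e-07). The melanin enzyme gene tyrp1 (ncbi_110500604) rose from 162 ± 15.1 to 373 ± 40.5 CPM (1.20, SE 0.10). All 3 loci of DCT, the dopachrome tautomerase of the same pathway, rose, by 1.93 (ncbi_110501902, SE 0.14), 1.14 (ncbi_110520165, SE 0.16) and 1.01 (ncbi_110520164, SE 0.095). The melanosome transporter genes Slc45a2 (ncbi_110523795), Oca2 (ncbi_110523057) and slc24a5 (ncbi_110506805) rose by 1.35 (SE 0.11), 1.49 (SE 0.33) and 0.57 (SE 0.14). A P protein-like locus (MSTRG.8428) rose by 2.04 (SE 0.28), from 45 counts in the wild type to 228 in the yellow mutant. A PMEL-like locus rose by 1.29 (ncbi_110494197, SE 0.092). Another was 2.82-fold higher (ncbi_110492024, 17 and 58 counts, adjusted p = 0.0317) and no longer past the threshold without yellow mutant replicate 1 (1.87-fold, adjusted p = 0.19), without wild-type replicates 2 or 3 (adjusted p = 0.0637 and 0.13) or in DESeq2 (0.0642). The second tyrp1 locus (ncbi_110531735), at 0.441 ± 0.197 and 0.942 ± 0.362 CPM, did not pass (adjusted p = 0.0666), but did without wild-type replicate 3 (0.0452) or yellow mutant replicate 3 (0.0478), or with library totals alone (0.0279). The KEGG Melanogenesis pathway, examined like all KEGG pathways after the values were seen, did not pass camera (224 genes, 56 higher, 45 lower, median 0.03, adjusted p = 0.409). In the same comparison the epidermal keratin and junction list was lower, with a median of -0.72.

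Regulators of melanophores, the black pigment cells, went both ways. Of 39 loci, 12 rose, 7 fell and 20 did not pass (13 higher and 8 lower adjusted over the list alone), and the list did not pass camera (median 0.08, adjusted p = 0.331). SOX10, a neural crest transcription factor gene, rose at all 4 of its loci, by 1.37 (ncbi_110538351, SE 0.094), 1.18 (ncbi_110486438, SE 0.10), 0.76 (ncbi_110485690, SE 0.12) and 0.50 (ncbi_110493441, SE 0.092). Both loci of MC1R, the melanocortin receptor of pigment cells, rose, by 1.35 (ncbi_110506598, SE 0.12) and 0.61 (ncbi_100499611, SE 0.17). The locus with the reference name mitfa (MITF, ncbi_110494592), the pigment cell transcription factor, rose from 4.21 ± 0.620 to 8.82 ± 1.66 CPM (log2 fold change 1.05, SE 0.17, adjusted p = 0.000286). The 3 further loci with a MITF product name did not pass, at 0.36 (ncbi_110527878, SE 0.22), 0.19 (ncbi_110492164, SE 0.14) and -0.15 (ncbi_110532443, SE 0.24). Loci that carry the MITF symbol but the product name transcription factor E3-like, another member of that factor family, stood at -0.46 (ncbi_110527898, SE 0.10, past the threshold), -0.29 (ncbi_110492696, SE 0.23) and -0.49 (ncbi_110531290, SE 0.40). The receptor gene kit rose at ncbi_110521672 (0.68, SE 0.10) and fell at ncbi_110524560 by 0.36 (SE 0.098). That decrease was not past the threshold with library totals alone (adjusted p = 0.193; 0.0522 to 0.257 over the settings in which it was lost), nor was that of ncbi_110527898 in 6 of the limma fits (0.0652 to 0.117). With library totals alone, ncbi_110527878 and ncbi_110492164 passed (adjusted p = 0.0467 and 0.0327). ERBB3 (ncbi_110528126), a neuregulin receptor gene that is also on the nerve list, fell by 1.58 (SE 0.094).

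**Figure D2:**
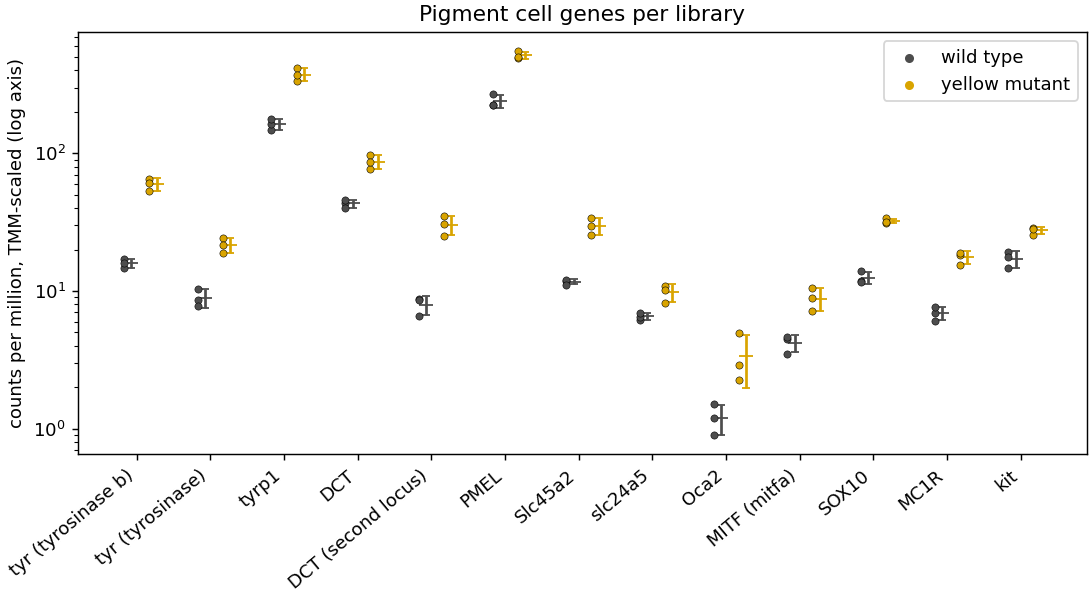
TMM-scaled CPM (log axis) of 13 pigment cell loci, with 1 point per library and bars for the mean ± SD of the 3 libraries of each phenotype. The loci were picked from all loci of the 11 pigment symbols. Those left out include kit ncbi_110524560, which fell, tyrp1 ncbi_110531735, whose phenotypes overlapped, and the MITF loci other than mitfa. All yellow mutant libraries lie above all wild-type libraries at each locus drawn, as for PMEL at 513 ± 30.5 against 239 ± 25.4 CPM.

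Lists for the other pigment cell types had medians above 0. Of 26 loci for pteridine synthesis and xanthophores (yellow pigment cells), 10 rose, 3 fell and 13 did not pass (11 and 3 adjusted over the list alone; median 0.19), and the list did not pass camera (adjusted p = 0.074). It did pass without yellow mutant replicate 2 (adjusted p = 0.023), with library totals alone (0.0467) and with members matched by both symbol and product name (0.0196). Gch1 (ncbi_110502330), which encodes the first enzyme of pteridine synthesis, rose from 49.9 ± 4.03 to 115 ± 19.03 CPM (log2 fold change 1.20, SE 0.11, adjusted p = 2.28e-06). Both SLC2A11 loci rose (ncbi_110535747, 2.01-fold, and ncbi_110525343, 2.09-fold), as did Qdpr (ncbi_110505140, 0.82, SE 0.094), the dihydropteridine reductase gene. Other entries of the list did not rise throughout. Under csf1r 2 of 4 loci rose and 1 fell (median 0.011), under aox5 0 of 2 rose and 1 fell, and under pax7 0 of 3 rose. Of 53 carotenoid and retinoid loci, 18 rose, 9 fell and 26 did not pass (18 and 10 adjusted over the list alone; median 0.22). The list passed camera at adjusted p = 0.0439, with adjusted p = 0.379 with an estimated correlation and 0.0928 without wild-type replicate 3. BCO2 (ncbi_110534238), which encodes a carotenoid-cleaving oxygenase, fell from 28.6 ± 1.08 to 12.6 ± 1.18 CPM (log2 fold change -1.18, SE 0.093, adjusted p = 4.71e-07). Of the 3 loci listed under bco2, 2 fell and 1 rose. The lipid storage genes PLIN2 (ncbi_110531797, 1.32, SE 0.11) and dgat2 (ncbi_110537459, 1.47, SE 0.14) and ttc39b (ncbi_110497341, 1.19, SE 0.12) rose. Of 48 loci for purine synthesis and iridophores (reflecting cells with guanine crystals), 26 rose, 2 fell and 20 did not pass (27 and 2 adjusted over the list alone; median 0.31, camera adjusted p = 0.000549, adjusted p = 0.52 with an estimated correlation). The purine synthesis genes ADSS (ncbi_110533991, 0.70, SE 0.075, and ncbi_110502989, 1.10, SE 0.13), PPAT (ncbi_110524565, 0.62, SE 0.077) and AIRC (ncbi_110524564, 0.53, SE 0.077) rose. Entries other than purine synthesis were mixed. Under pnp4a 3 of 7 loci rose and 1 fell (median 0.074), and the single ltk, alkal2 and mpv17 loci did not pass. Under fhl2 3 of 4 loci rose and under tfec 1 of 2, with 0 lower. Among KEGG pathways, Purine metabolism (287 genes, 98 higher, 53 lower, median 0.10, adjusted p = 0.126) and Retinol metabolism (64 genes, 12 higher, 16 lower, median -0.003, adjusted p = 0.665) did not pass. Keratin and junction genes fell in these libraries, as given above.

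The Wnt signalling list, whose pathway takes part in pigment cell specification, had a median slightly above 0. Of 49 loci, 14 rose, 3 fell and 32 did not pass (14 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.0364, adjusted p = 0.274 with an estimated correlation and 0.0505 without wild-type replicate 3). Among the secreted modulators, SFRP1 (ncbi_110525892) rose by 0.99 (SE 0.094), SFRP2 (ncbi_110534319) by 0.92 (SE 0.13) and Dkk3 (ncbi_110498847) by 1.06 (SE 0.13). A wnt11 locus (ncbi_110533847), which encodes a Wnt ligand, had 3 counts in the wild type and 154 in the yellow mutant, a scaled ratio of 42.4 (95% counting interval 14.2 to 208). It kept 1 wild-type count without wild-type replicate 2. The KEGG Wnt signaling pathway, examined after the values were seen, did not pass camera (344 genes, 76 higher, 67 lower, median 0.02, adjusted p = 0.83).

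Genes of epidermal keratins and cell junctions were lower in the yellow mutant. Of 81 loci, 3 rose, 59 fell and 19 did not pass (5 and 59 adjusted over the list alone), with a median log2 fold change of -0.72 (camera adjusted p = 1.17e-16, adjusted p = 0.225 with an estimated correlation). Besides krt13, the locus with the product name Keratin 12 (ncbi_100136069) fell from 3159 ± 92.1 to 1072 ± 72.6 CPM (log2 fold change -1.56, SE 0.092). Claudin 30 (CLDN4, ncbi_100642186), a tight junction gene, fell from 481 ± 54.2 to 120 ± 8.74 CPM (4.01-fold lower), and periplakin (PPL, ncbi_110485330), a cytolinker of the cornified envelope, fell by 3.33 (SE 0.18). All 5 loci of desmoplakin (dsp) and all 3 of E-cadherin (cdh1) fell, with medians of -0.83 and -1.15. Of 33 loci listed under a krt symbol, 20 fell and 2 rose. Counts of near-identical keratin loci are uncertain, because the way in which reads shared between copies were counted is not given in the sources used here.

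Mucous cell genes, a marker set for the mucus-secreting cells of fish epidermis, were also lower. Of 80 loci, 11 rose, 37 fell and 32 did not pass (12 and 39 adjusted over the list alone; median -0.41, camera adjusted p = 0.000143, adjusted p = 0.379 with an estimated correlation). Most members were gel-forming mucin loci, of which 34 of 69 fell and 8 rose. Mucin-5AC-like loci fell, at -2.33 (MSTRG.22436, SE 0.11), -2.28 (ncbi_110534375, SE 0.17) and -4.09 (ncbi_110533162, SE 0.33), and Muc2 (ncbi_110506632, product name mucin-5B-like), the most abundant of the 4, fell from 188 ± 1.40 to 90.5 ± 5.46 CPM (-1.06, SE 0.077). With members matched by both symbol and product name, 16 loci were left and the list did not pass (median -0.82, adjusted p = 0.183). Both loci of agr2, a secretory cell marker, rose (median 0.57).

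**Figure D3:**
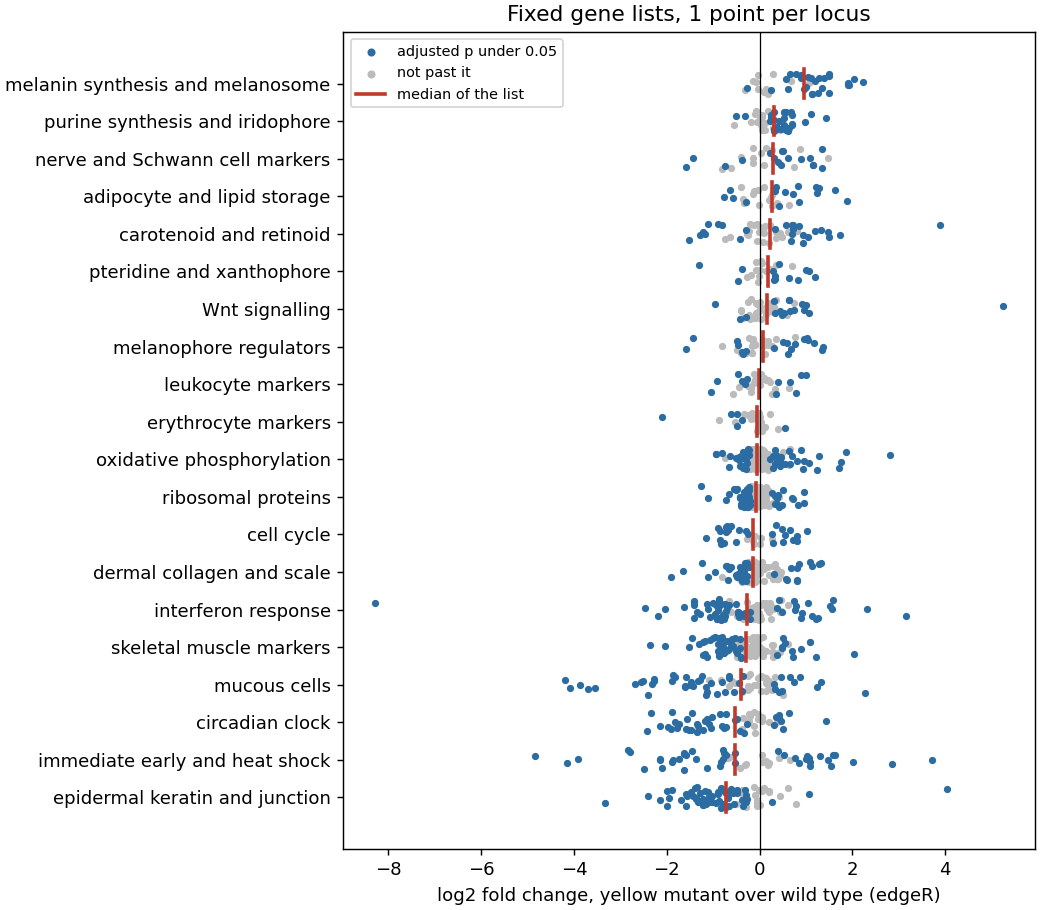
Log2 fold changes (x axis, yellow mutant over wild type, edgeR with TMM scaling) of the members of the 20 gene lists, with 1 point per locus, blue where the adjusted p was under 0.05, and a red bar at each list's median. Medians run from 0.95 for the melanin list to -0.72 for the epidermal list; the 6 medians between -0.14 and 0 lie above 0 with library totals alone, namely those of the leukocyte, erythrocyte, oxidative phosphorylation, ribosomal, cell cycle and dermal lists.

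Lists for other tissues and cells that dorsal skin can hold had medians between -0.30 and 0.28. Of 89 dermal collagen and scale loci, 12 rose, 27 fell and 50 did not pass (the same counts adjusted over the list alone; median -0.14, camera adjusted p = 0.392). ALPL, the alkaline phosphatase gene of mineralizing tissue, fell at both named loci (ncbi_110494449, -1.91, SE 0.11; ncbi_110494447, -1.66, SE 0.16), while the matrix metalloproteinase genes MMP9 (ncbi_110492670, 1.33, SE 0.13) and MMP2 (ncbi_100135793, 0.81, SE 0.079) rose. Skeletal muscle markers were lower: of 95 loci, 11 rose, 37 fell and 47 did not pass (11 and 39 adjusted over the list alone; median -0.30, camera adjusted p = 0.00692, adjusted p = 0.715 with an estimated correlation). The fast myosin MYH4 (ncbi_110532987) fell from 154 ± 34.5 to 30.2 ± 7.57 CPM (log2 fold change -2.35, SE 0.18), and Atp2a1 (ncbi_110537826), the calcium pump gene of fast muscle, fell by 0.79 (SE 0.083). Also lower were acta1 (ncbi_110529317, product name actin, alpha cardiac muscle 1-like, -2.04, SE 0.19) and OCM (ncbi_110486849, product name parvalbumin, thymic CPV3-like, -1.18, SE 0.12). Other entries did not fall: under the fast troponin gene tnni2 6 of 12 loci rose and 0 fell (median 0.385), and under tnnt3 0 of 4 passed. The muscle list did not pass with members matched by both symbol and product name (adjusted p = 0.183).

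Erythrocyte markers did not pass (27 loci, 1 higher, 5 lower, 21 not past; 1 and 2 adjusted over the list alone; median -0.05, camera adjusted p = 0.46). The haemoglobin loci hbb (ncbi_110538444, -2.10, SE 0.27), hba (ncbi_110538451, -0.62, SE 0.10) and hbb1 (ncbi_110538446, -0.48, SE 0.15) fell and hbb4 (ncbi_100136291, 0.55, SE 0.14) rose. The decrease of hbb1, whose groups overlapped, was not past the threshold without wild-type replicates 1 or 2 (adjusted p = 0.0759 and 0.093) or yellow mutant replicates 2 or 3 (0.111 and 0.0635), nor with library totals alone (0.137), and lay between 0.0635 and 0.289 over the settings in which it was lost. Leukocyte markers gave 6 higher, 6 lower and 20 not past among 32 loci, with the same counts adjusted over the list alone (median -0.00, mean 0.02, camera adjusted p = 0.904). MPO (ncbi_110509901), with the product name eosinophil peroxidase, fell by 1.04 (SE 0.076), and the macrophage receptor Marco (ncbi_110501689) rose by 0.90 (SE 0.093). The lysozyme loci ncbi_110485996 (-0.93, SE 0.098) and LYG2 (ncbi_110488547, -0.46, SE 0.076) fell. Under lyz, however, 2 of 6 loci rose and 2 fell (median 0.239), and under mpx 1 of 3 rose and 1 fell. Adipocyte and lipid storage genes were higher (30 loci, 12 higher, 4 lower, 14 not past, the same counts adjusted over the list alone; median 0.28, camera adjusted p = 0.0492, adjusted p = 0.52 with an estimated correlation). That call was lost without wild-type replicate 3 (adjusted p = 0.0612) or yellow mutant replicates 1 or 2 (0.109 and 0.0539), and in the settings in which it was lost the adjusted p ranged from 0.0539 to 0.52. The lipid synthesis genes SCD (ncbi_110531805, 1.88, SE 0.18), SCD1 (ncbi_110530485, 0.84, SE 0.087) and FASN (ncbi_110499230, 0.83, SE 0.12) and the lipase gene LPL (ncbi_110530805, 1.29, SE 0.18) rose. Of the 6 loci listed under lpl, 2 rose and 2 fell. Nerve and Schwann cell markers did not pass (30 loci, 13 higher, 4 lower, 13 not past; 13 and 5 adjusted over the list alone; median 0.28, camera adjusted p = 0.46). Among them, ERBB3 (ncbi_110494311) fell by 1.43 (SE 0.14), MBP (ncbi_110489647), a myelin gene, fell by 0.75 (SE 0.14) while 3 of the 4 loci listed under mbp rose (median 0.45), and Pmp22 (ncbi_110487097), another myelin gene, rose by 0.46 (SE 0.084).

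Genes of the circadian clock were lower in the yellow mutant. Of 57 loci, 8 rose, 33 fell and 16 did not pass, with the same numbers higher and lower adjusted over the list alone (median -0.53, camera adjusted p = 6.57e-11, adjusted p = 0.225 with an estimated correlation). Tef (ncbi_110538372), a clock output transcription factor gene, fell from 84.8 ± 13.7 to 15.8 ± 1.70 CPM (log2 fold change -2.43, SE 0.12, adjusted p = 1.21e-08). The nuclear receptor genes that repress the clock fell at ncbi_100135954 (NR1D2, -1.81, SE 0.098) and ncbi_110528196 (Nr1d2, product name nuclear receptor subfamily 1 group D member 1-like, -1.59, SE 0.083). Over all loci listed under nr1d1, nr1d2, ciart and per1, 5 of 6, 4 of 4, 4 of 4 and 3 of 3 fell, with medians of -1.34, -1.27, -1.21 and -1.47. Other entries did not fall throughout: tef had 1 locus higher and 2 lower of 5 (median -0.109), cry1 1 and 3 of 5 (-0.80), per2 1 and 0 of 2 (0.40), bhlhe40 0 and 3 of 4 (-0.30), bhlhe41 1 and 0 of 2 (0.17), arntl 2 and 1 of 7 (0.043) and clock 1 and 0 of 4 (-0.18), and the single cry2 locus rose (0.41). The list includes 10 loci under nfil3, of which 8 fell, and 4 of the 10 carry filaggrin product names, such as ncbi_110485671 (NFIL3, product name filaggrin-2-like, -1.73, SE 0.095), filaggrin being a protein of the outer epidermis. With members matched by both symbol and product name, 22 of 37 loci fell and 5 rose (adjusted p = 7.46e-08). The KEGG Circadian rhythm pathway was also lower (79 genes, 17 higher, 32 lower, median -0.22, adjusted p = 0.0351, adjusted p = 0.454 with an estimated correlation). Keratin and junction genes fell in the same libraries (median -0.72).

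The immediate early and heat shock list split into genes that fell and genes that rose. Of 56 loci, 17 rose, 27 fell and 12 did not pass (20 and 28 adjusted over the list alone), and the list as a whole did not pass camera (median -0.53, adjusted p = 0.394), although it did without yellow mutant replicate 3 (adjusted p = 0.0102) and with members matched by both symbol and product name (0.0211). Divided by function, a division made after the values were seen, 24 of 31 immediate early loci fell and 1 rose (median -1.46), while 16 of 25 heat shock and chaperone loci rose and 3 fell (median 1.001). The nuclear receptor gene nr4a1 (ncbi_110494169) fell from 38.5 ± 4.06 to 5.54 ± 0.839 CPM (log2 fold change -2.79, SE 0.12) and DUSP1 (ncbi_110504465), a MAP kinase phosphatase gene, from 78.4 ± 8.19 to 11.1 ± 3.28 CPM (-2.82, SE 0.16). A further HSP90 locus, hsp90a.1 (ncbi_110522488), rose from 12.01 ± 1.26 to 86.9 ± 8.91 CPM (2.86, SE 0.10).

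The interferon response list was lower. Of 104 loci, 17 rose, 46 fell and 41 did not pass (17 and 48 adjusted over the list alone; median -0.27, camera adjusted p = 0.00201, adjusted p = 0.379 with an estimated correlation). The ubiquitin ligase family listed under trim25 made up 53 of these loci and 28 of those that fell. Among the other 51 loci, counted after the values were seen, 12 rose and 18 fell (median -0.09). With members matched by both symbol and product name the list did not pass (36 loci, median -0.05, adjusted p = 0.696). DHX58 (ncbi_100499613), a regulator of RNA virus sensing, fell from 37.9 ± 5.91 to 8.33 ± 0.719 CPM (log2 fold change -2.18, SE 0.12). Loci with the product name fish virus induced TRIM protein fell, at -2.04 (TRIM25, ncbi_110503178, SE 0.091) and -1.41 (TRIM25, MSTRG.5328, SE 0.081). Another TRIM25 locus (ncbi_110521266) had 365 counts in the wild type and 1 in the yellow mutant, a scaled ratio of 442 (95% counting interval 78.9 to 17500). That count came from yellow mutant replicate 1, without which the locus was at least 103-fold lower. The epidermal keratin and junction list was lower in the same libraries (median -0.72).

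Cell cycle genes went both ways (33 loci, 11 higher, 15 lower and 7 not past, with the same numbers higher and lower adjusted over the list alone; median -0.14, camera adjusted p = 0.394). The replication helicase genes mcm2, mcm3, mcm5 and mcm6 rose at all 6 of their loci (median 0.76), including mcm2 (ncbi_110528595, 1.02, SE 0.082; ncbi_110493296, 0.80, SE 0.074) and mcm5 (ncbi_110486535, 0.81, SE 0.083). The 25 loci other than mcm and pcna gave 15 lower and 3 higher (median -0.45), among them the mitotic kinesin kif11 (ncbi_110529943), lower by a log2 fold change of -0.86 (SE 0.088). This division was also made after the values were seen. Oxidative phosphorylation genes did not pass (137 loci, 25 higher, 24 lower, 88 not past; 25 and 23 adjusted over the list alone; camera adjusted p = 0.46), and their median (-0.05) and mean (0.07) differed in sign. Of 11 loci of succinate dehydrogenase, which links the citric acid cycle to respiration, 4 rose, 1 fell and the others did not pass (median 0.155). Those that rose were an sdhb locus (ncbi_110492247, 2.81, SE 0.12) and 3 sdha loci (ncbi_110520756, 1.87, SE 0.14; ncbi_110520843, 1.24, SE 0.084; ncbi_110496683, 0.54, SE 0.091), whereas another sdhb locus fell (ncbi_110528062, -0.94, SE 0.18); ncbi_110496683 and ncbi_110528062 were chosen after their values were seen. UQCRH (ncbi_110508937, 0.95, SE 0.079), a subunit of respiratory complex III, rose. Ribosomal protein genes did not pass (173 loci, 15 higher, 45 lower, 113 not past; 15 and 38 adjusted over the list alone; median -0.07, camera adjusted p = 0.46). RPL3 (ncbi_110486633) fell from 1185 ± 61.0 to 545 ± 23.9 CPM (log2 fold change -1.12, SE 0.086) and rps28 (ncbi_110508919) fell by 1.25 (SE 0.081), whereas RPL7L1 (ncbi_100301843) and rps27 (ncbi_110524214) each rose by 0.97 (SE 0.072 and 0.083).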

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

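Library totals without TMM, limma at a pseudocount of 0.5 and members matched by both symbol and product name were chosen after the data were seen. The total of 13737 genes stayed within 1.5 times under all settings but the fold threshold: 10396 with a mean FPKM of at least 2, 11124 with DESeq2 and 11674 to 12553 without 1 library. The direction split did not. Settings that left FPKM or counts unscaled moved the median of all genes by 0.14 to 0.20 and called fewer genes lower than the 7079 with TMM: 4062, 4094 and 4099 with limma at pseudocounts of 0.1, 0.5 and 1, 4421 with TPM, 3991 without a variance trend, 4183 with library weights (10098 higher) and 4544 with library totals alone (10805 higher). With size factors edgeR called 7049 lower. An absolute log2 fold change of at least 1 left 3515 genes (1477 higher, 2038 lower), as its construction requires.

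The gap between the lowest correlation within and the highest across phenotypes (0.0447) stayed above 0: 0.0497, 0.041 and 0.0368 with pseudocounts of 0.1, 0.5 and 1, 0.0175 without a filter, 0.0605 with a mean FPKM of at least 2, 0.0406 with quantile normalization, 0.0405 with size factors in limma, and 0.0424 to 0.0497 without 1 library. The cause was not tested. Camera called 10 of the 20 lists, 0 with an estimated correlation and 7 to 11 without 1 library, the fewest without wild-type replicate 3; these counts include lists gained, such as the immediate early list without yellow mutant replicate 3. The ribosomal list was reversed with quantile normalization (median 0.089, adjusted p = 0.0474), and the cause was not tested. The carotenoid list also lost its call with library totals alone (adjusted p = 0.0582, range over settings 0.0582 to 0.379 where lost). Fry passed the melanophore regulator, pteridine and dermal lists besides 9 of the 10, and not the muscle list. DESeq2 was not run for lists. No named gene was reversed. The deviations of same-numbered libraries were weakly correlated (0.08, 0.0137 and 0.0557, against at most -0.0205, 0.00739 and 0.00724 with another number), so each correlated best with its own number, a hint from the data and not the design, and the second principal component set replicate 1 apart in both phenotypes. The replicate block called 13868 genes and changed no call of a list or named gene. Depth limits folds of genes with fewer than 10 counts in a phenotype, such as POLR2C.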

Other observations

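The KEGG comparison, the contrast of the melanin list with other lists, the size of the keratin shift, the search for a library out of place and the size-matched random sets were tests chosen after the results were seen. The other tests were fixed before their results. Bootstrap intervals in this section resample loci, which are not independent, and not libraries. They may be too narrow and do not measure the spread between libraries. Among 232 KEGG pathways named in the deposited table with at least 15 tested genes, 21 passed camera with the preset correlation, 14 higher and 7 lower in the yellow mutant, and 0 passed with an estimated correlation. Ribosome biogenesis, the assembly of ribosomes in the nucleolus, was foremost: 74 of 114 genes rose and 5 fell (median log2 fold change 0.57, adjusted p = 1.22e-17, adjusted p = 0.0537 with an estimated correlation). Other pathways that passed included the spliceosome, with 126 of 272 genes higher and 13 lower (median 0.23, adjusted p = 2.36e-05), 22 and 2 of 44 for RNA polymerase (0.40), 31 and 3 of 60 for aminoacyl-tRNA synthesis (0.31) and 29 and 1 of 40 for protein export (0.44). Each of these 4 had adjusted p = 0.432 or 0.436 with an estimated correlation. The Ribosome pathway did not pass (47 higher and 51 lower of 240, median -0.03, adjusted p = 0.705), nor did mRNA surveillance (0.057) or basal transcription factors (0.265). Terpenoid backbone synthesis, which makes the precursors of sterols, had 20 of 32 genes higher and 0 lower (median 0.40, adjusted p = 0.0011, adjusted p = 0.432 with an estimated correlation). Lower pathways included TNF signalling, an inflammatory pathway (32 higher and 96 lower of 261, median -0.19, adjusted p = 0.0162, adjusted p = 0.545 with an estimated correlation), and autophagy as named for other eukaryotes (6 and 30 of 64, median -0.28, adjusted p = 0.00759, adjusted p = 0.432 with an estimated correlation), whereas the animal autophagy pathway did not pass (47 higher and 111 lower of 313, median -0.12, adjusted p = 0.0764). Among pathways close to a fixed list, DNA replication was higher (25 and 3 of 51, median 0.29, adjusted p = 0.0013, adjusted p = 0.728 with an estimated correlation) and adipocytokine signalling lower (16 and 60 of 157, median -0.22, adjusted p = 0.0423, adjusted p = 0.644 with an estimated correlation), while the cell cycle (adjusted p = 0.899), oxidative phosphorylation (0.509), tight junction (0.174) and RIG-I-like receptor (0.16) pathways did not pass. Antigen processing and presentation was higher in camera (44 higher and 20 lower of 105, median 0.17, adjusted p = 1.66e-06, adjusted p = 0.545 with an estimated correlation), whereas the fixed interferon list was lower. Keratin and junction genes fell in these libraries.

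Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) called as many genes in edgeR, 13737 against a highest of 0 in the others, where 249 to 461 genes had an unadjusted p under 0.05 (15891 in the real split; DESeq2 was not run on the other splits). With 10 splits the share cannot fall below 0.05, and no more can be said.

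The yellow mutant had more RNA of melanin genes, with a median log2 fold change of 0.95 (camera adjusted p = 6.57e-11, adjusted p = 0.379 with an estimated correlation). A lower share of epidermal cells alone, with all other cell types kept in proportion, would raise the markers of those types alike. The melanin median exceeded that of 273 dermal, muscle, erythrocyte, leukocyte and nerve loci (-0.123) by 1.072 (95% bootstrap interval 0.76 to 1.275). It exceeded those of the separate lists by 0.667 (0.222 to 1.056) for nerve, whose median was 0.28, up to 1.249 (0.915 to 1.518) for muscle, whose median was -0.30. For the adipocyte list, left out of the pool, whose median was 0.28, the difference was 0.671 (0.324 to 1.044). The list medians were known when this contrast was chosen, so its sign was fixed in advance. These medians do not show an equal rise, but other differences in tissue composition were not tested and stay open. The smaller keratin share of the yellow mutant shifts every other gene by only 0.0603 on the log2 scale, too little for the melanin median of 1.146 (0.847 to 1.338) with library totals alone; a test fixed earlier, which left 63 keratin loci out of the totals, was void for the same reason. In addition, 0 of 6 libraries lay nearest to the other phenotype, whereas a single wrong label would need at least 1. An exchange of both whole groups would leave no trace in these tests and stays open, as does a difference between the phenotypes themselves, which was not tested further.

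The circadian list was lower in the yellow mutant (camera adjusted p = 6.57e-11, adjusted p = 0.225 with an estimated correlation), and 24 of 31 immediate early loci, a group split off after the values were seen and not tested as one, fell. A different time of day at sampling would be expected to move the limbs of the clock apart. The arntl and clock loci minus the per1, per2, nr1d1, nr1d2, tef and ciart loci gave 1.212 (95% bootstrap interval 0.476 to 1.661). However, the first limb was not above 0 (median -0.036, 11 loci, 3 higher and 1 lower). The second was at -1.248 (24 loci, 2 higher and 18 lower). Both limbs are members of the circadian list, so the low second limb repeats its decrease. The first limb also took in loci with arntl protein 2 (-1.525, 1.44, -0.037) and npas2 (0.308, -0.375) product names. Its other loci stood at 0.512, 0.195, 0.043 and -0.036 for arntl protein 1 and -0.251 and -0.1 for clock. The sign of its median depends on which of these are counted. Sampling time and phenotype therefore cannot be told apart here. A different stress or handling state might lower glucocorticoid-responsive genes. The 53 loci matched to 12 such symbols, 14 of them matched to zbtb16, had a median of -0.306 (-0.726 to 0.132, with 10 higher and 23 lower). The match also took in related genes, such as BCL6B loci (0.866 and 0.833) and a zinc finger and BTB domain-containing protein 32-like locus (-1.858). The bound written for that test counted an interval that holds 0 as evidence against this explanation, which was wrong because the interval excludes neither 0 nor a decrease, so it also stays open, as does the phenotype itself.

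A total of 51 tested loci were detected in only 1 phenotype, 27 in the wild type and 24 in the yellow mutant, with at most 3 counts in one group and at least 60 in the other; timm10 (ncbi_110497210), chosen after its values were seen, had 364 counts in the wild type and 0 in the yellow mutant. Reads that move between near-identical loci, for instance where alleles differ between the phenotypes, may account for part of them. Of 43 with a product name, 22 (51.2%) had a locus of the same product called in the opposite direction. Among other called genes, 2675 of 13176 did (20.3%, Fisher's exact test, one-sided p = 7.07e-06). Random sets matched on family size had a median of 11, and 0 of 10000 reached 22 (share 1e-04, the smallest they can give). Loci were paired by product name alone, and neither sequence similarity nor shared reads were measured. The test therefore cannot tell moved reads from opposite changes in the RNA of related genes. A stretch of chromosome that differs between the phenotypes could place such loci side by side, and 7 lay within 5 tested loci of another. Of 10000 random sets, 1 reached that number (share 2e-04 with the observed set counted in). Only 31 of the 51 (60.8%) have a position in the reference, so that result covers those loci alone. The random sets were matched on mean count and not on gene family, so neighbouring copies of the same family could also give it. This explanation therefore stays open.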
